A study of Homo sapiens with 2 samples.

How the data were processed

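RNA bound to the splicing factor Tra2β was compared with RNA recovered by control rabbit IgG in HCT116 cells, an established human colon cancer cell line. Per the labels' protocols, lysates were incubated for 2 h with protein A beads that carried 3 µg of either antibody, the beads were treated with DNase and then proteinase, and the bound RNA was extracted. For each precipitate, 400 ng of RNA was amplified into Cy3-labelled cRNA and hybridised to a 1-colour Agilent whole human genome array. There was 1 array per group, 2 arrays in all, and both lay on the same slide, so no spread between replicates could be measured and no p-value is given. The number of arrays limits the precision of every ratio.

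The deposited scanner files hold intensity values of 45015 spots per array, 43376 of them outside the control spots. Per the file headers they were made with Agilent Feature Extraction 9.5.3.1, and the submitters' processing notes name the same program as version 9.5. Per the file headers the array annotation refers to human genome build hg17, and the processed signal is a background-subtracted and detrended intensity, with low values replaced by a positive surrogate and no scaling between arrays. The authors also deposited a value table on a log2 scale with 21666 rows, 22 of them control probes. Set against the scanner values, each of its columns equalled the log2 processed signal less a constant, 9.51 for the IgG IP and 2.36 for the Tra2β IP, within 0.01 for 100.0% of rows, and the column medians were -0.19 and -0.38. The scale of that table is therefore known, genes were not centred, and its direction is that of the signal.

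Each array's log2 processed signal was reduced by its own 75th percentile over probes outside the controls, and all ratios are the Tra2β IP minus the IgG IP on this scale. Spots of 1 probe were averaged, and spots marked as outliers by the scanner software were left out, 66 on the IgG array and 49 on the Tra2β array, which removed 3 probes. No spot was saturated (0 on either array). A probe was counted as well above background where most of its spots carried the scanner software's mark for this. Probes were named by matching their accession, without version, to the RefSeq gene table of assembly GRCh38.p14, used for names alone because the build differs. Of 40997 probes, 23432 matched 1 gene, 0 matched several and 17565 matched none, among them 1712 of 25144 with a RefSeq accession. A gene took the value of the probe with the highest mean log2 signal among those well above background on both arrays. A gene well above background on 1 array has only a bound. Its at-least fold sets the bright value against the higher of the dim array's lowest signal well above background and the probe's own value, and it is left out where it is under 1. For genes with both values a 2-fold size rule (log2 ratio of 1 or -1) was used as a description.

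Depth on an array is signal over background. The median of 153 negative control spots was 4.37 on the IgG array and 3.46 on the Tra2β array, and the lowest signal well above background was 19.8 and 16.3. Probes with at least 5 spots gave the technical spread. Over 47 such probes well above background on both arrays, the median SD of log2 signal was 0.05 in the IgG IP and 0.17 in the Tra2β IP, which makes an SD of 0.17 for a ratio. It covers spot-to-spot error within an array alone.

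The gene lists were chosen before the data were examined, as were the ratio, the size rule, the rule for named genes and most alternatives. The 22 lists were Tra2 targets, the BCL2 family, caspases with inhibitors of apoptosis and death receptors, SR proteins, hnRNPs, core spliceosome, ribosomal proteins, nuclear respiratory chain genes, replication histones, ZNF zinc fingers, cell cycle, DNA repair, coiled-coil proteins, chromatin regulators, chaperones, immediate-early genes, secretory and membrane proteins, Wnt and colorectal cancer genes, colon epithelium, markers of other cell types, noncoding nuclear RNAs, and housekeeping genes. A list's median ratio was placed among the medians of 10000 random lists of the same size, matched on mean log2 signal in 20 bins. A median in the outer 2.5% on either side is described as standing apart, and it is a description of these arrays. Lists with fewer than 3 genes measured on both arrays have no percentile. After the data were seen, the share of each list detected in the Tra2β IP was placed in the same way among lists matched on IgG signal. It was also placed among lists that drew, for each member, 1 of its 50 nearest genes in IgG signal.

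Genes were named by this rule: the Tra2 targets and the anti-apoptotic BCL2 members whatever their value; the 12 highest and 8 lowest ratios among genes whose brighter signal reached the median of that array's probes well above background and whose measured probes went the same way; the 6 genes of the Tra2β IP alone and the 4 of the IgG IP alone with the largest at-least fold; and up to 4 members of each list with the largest size of ratio. Names outside the rule are marked where they appear. Of the genes under this rule, 2 are not reported here.

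Alternatives were the median of all probes, quantile normalization, normexp background correction (offset of 50), the deposited value table, the median over a gene's probes, no filter or a stricter filter on dim probes, leaving out probes with an outlier spot, a 4-fold size rule, another detection mark, and 5 bins for the random lists. The files hold no mean spot signal, so normexp was run on the median spot signal. Added after the data were seen were unscaled signals, the percentile over probes well above background on both arrays, and genes whose probes all went the same way. The 75th percentile of the Tra2β array, 5.15, lay below its lowest signal well above background, which is why the percentile over detected probes was added.

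On simulated arrays with the SD of a ratio from repeated spots and 1830 genes measured, the size rule found 100.0% of genes changed by log2 1.5, -1.5 or 3, and 92.0% of those changed by -3. It called 0% of unchanged genes. The simulated noise was the spot-to-spot SD alone, and changed genes were drawn from bright genes. Error between arrays, from the scaling or between probes of a gene was not simulated, so these shares do not measure the error of the counts. Unmatched and matched probes were compared within 5 bins of IgG signal, with bootstrap ranges from resampled probes. Of 100 simulated lists without a shift 5.0% stood apart, and of those shifted by log2 2 100.0% did. Scripts used Python 3.11.15 with numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3, and R 4.3.3 with limma 3.58.1 for normexp. Motif content of transcripts was not analysed here, since no transcript sequences were used.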

Results

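RNA that came down with Tra2β, an SR-like splicing factor that binds GAA-rich RNA, was set against RNA recovered with control IgG from HCT116 colon cancer cells, to find mRNAs associated with Tra2β. Each precipitate was measured on 1 array, so no ratio has a replicate check, and a ratio's SD from repeated spots was 0.17 on the log2 scale. The arrays differed widely in depth. In the IgG IP 24261 of 40997 probes (59.2%) were well above background, with a median signal of 60.4. In the Tra2β IP 3852 probes (9.40%) were, with a median signal of 3.67, close to its negative controls at 3.46. Named genes were well above background in 11512 cases in the IgG IP and in 1686 cases in the Tra2β IP. Of 10 control probes for E1A, which this platform provides as a spike-in for labelling, 8 were well above background on the IgG array and 1 on the Tra2β array. Probes without a RefSeq match carried 24.7% of all signal in the IgG IP and 87.8% in the Tra2β IP.

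**Figure D1:**
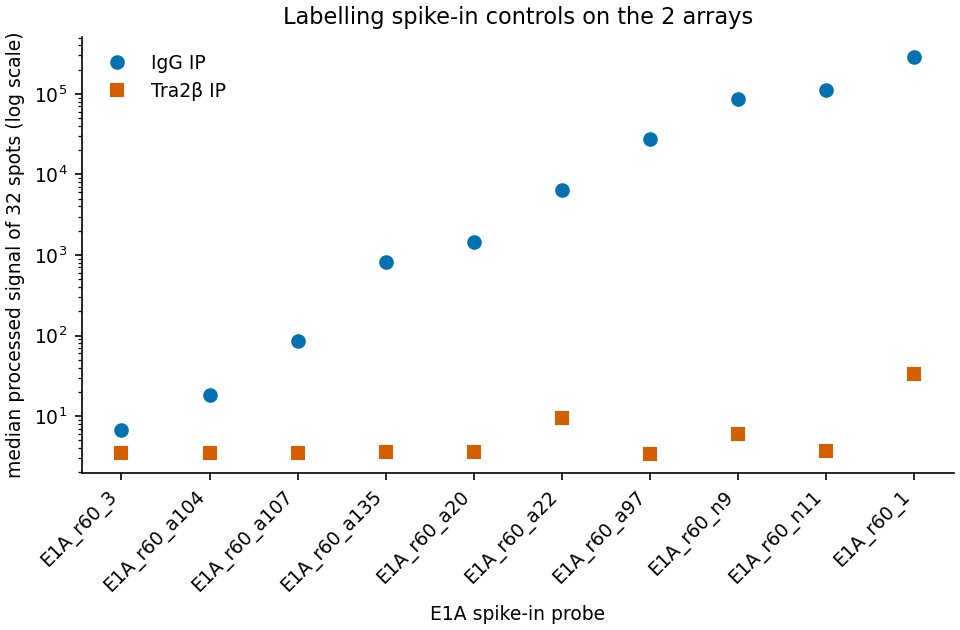
Median processed signal of 32 spots (y axis, log scale) for each of the 10 E1A spike-in probes (x axis) on the IgG array (circles) and the Tra2β array (squares). The IgG array spans 6.76 to 290009, and 9 of 10 probes stay below 10 on the Tra2β array.

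**Figure D2:**
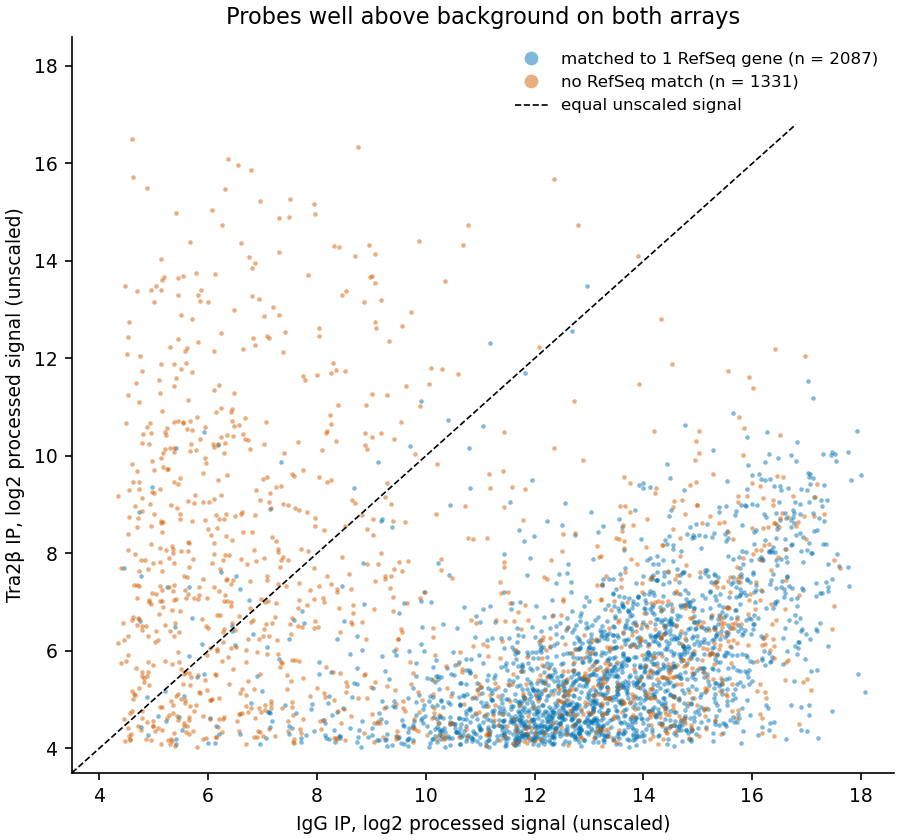
Unscaled log2 processed signal in the Tra2β IP (y axis) against the IgG IP (x axis) for the 3418 probes well above background on both arrays, 2087 matched to a RefSeq gene (blue) and 1331 unmatched (orange). Of the unmatched probes 442 lie above the dashed line of equal signal, and of the matched probes 29 do.

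High ratios belonged to genes that were dim in the IgG IP and bright in the Tra2β IP. NYX, which encodes the retinal protein nyctalopin, had a signal of 60.6 in the IgG IP and 1448 in the Tra2β IP, a log2 ratio of 11.73, and TIGD1, derived from a transposable element, had a ratio of 11.53. The retinoic acid receptor gene RARA stood at 11.28, CC2D2B at 11.20, the orphan receptor gene GPR25 at 10.38 and the G protein subunit gene GNAZ at 9.91. EME1, a subunit of a DNA junction endonuclease, had a ratio of 9.69, CRCT1 9.20, the ghrelin receptor gene GHSR 9.02, the serine racemase gene SRR 8.92 and LENG8 8.80. All 11 were also brighter in unscaled signal in the Tra2β IP, from 1.66 (LENG8) to 4.58 (NYX) on the log2 scale. Other probes did not share these levels: a second RARA probe had a signal of 2617 in the IgG IP and a second GNAZ probe 4414, and neither was well above background in the Tra2β IP. Without the filter on dim probes these brighter probes stood for their genes, at -0.45 and -3.13, from Tra2β signals (13.5 and 3.54) that allow only a bound. A second LENG8 probe measured on both arrays had a ratio of 4.29 and was dimmer in unscaled signal in the Tra2β IP (125 and 17.2). Another LENG8 probe (759 in the IgG IP) and a second TIGD1 probe (76.5) were not well above background in the Tra2β IP. A second CRCT1 probe was well above background on neither array.

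The lowest ratios belonged to mRNAs that were very bright in the IgG IP, which the detection floor requires. No probe with a ratio had a Tra2β signal under 16.3, so a very low ratio needs a bright IgG signal. ATP5MC3 (18.3), RPS3, MIF and RPLP0P2 (20.8) lay close to that floor in the Tra2β IP. Genes not detected there, such as GSTP1, have only a bound and are not ranked here. The ribosomal protein gene RPS3 had a signal of 151405 in the IgG IP and 18.5 in the Tra2β IP, a log2 ratio of -5.85. NBPF11, of a gene family with many near-identical copies, stood at -5.54, the cytokine gene MIF at -5.52 and the ribosomal protein pseudogene RPLP0P2 at -5.36. ATP5MC3, a subunit of ATP synthase, had a ratio of -5.28, RPS28 -5.26, the thymidine kinase gene TK1 -5.22 and NBPF3 -5.00. These 8 were lower in the Tra2β IP under each scaling tried, and the values of the NBPF genes and RPLP0P2 are uncertain because related copies can share a probe. A second measured probe stood at -2.15 for RPS28 and at -2.21 for NBPF3.

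**Figure D3:**
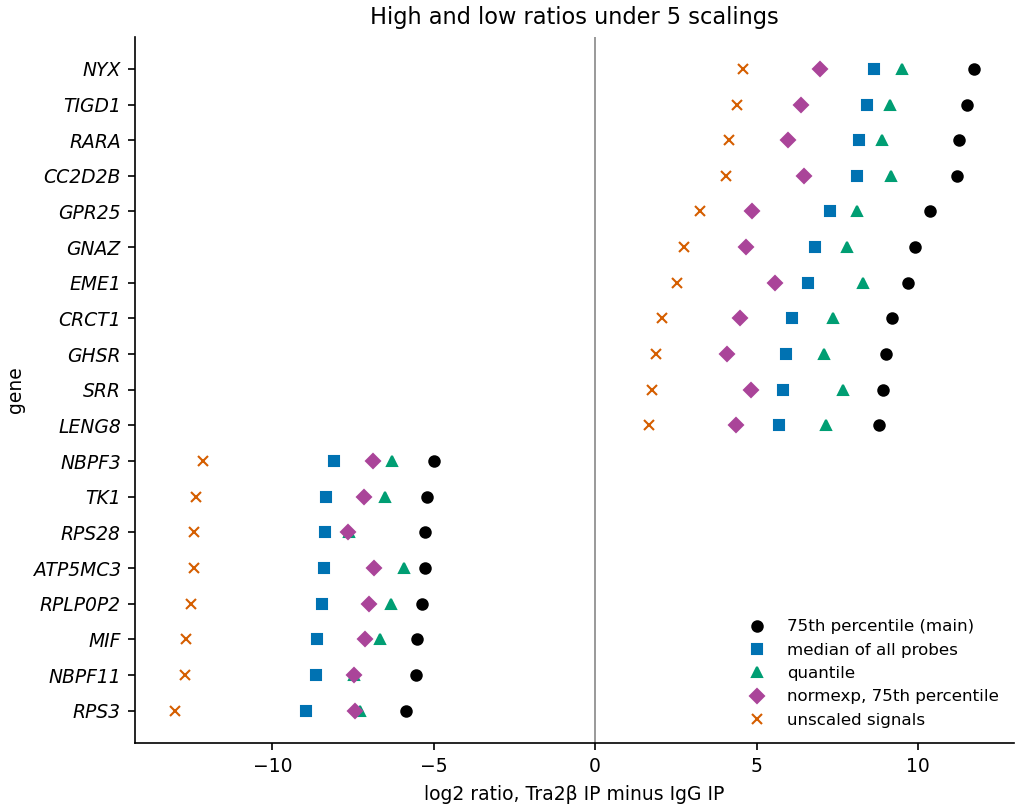
Log2 ratio of the Tra2β IP over the IgG IP (x axis) for 11 genes with high ratios and the 8 with the lowest under the naming rule (y axis), with 1 symbol per scaling and 1 array per group. Every symbol of the 11 lies above 0 and every symbol of the 8 below 0, from 11.73 for NYX to -5.85 for RPS3 under the main scaling.

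Over the 1661 genes well above background on both arrays, 333 were at least 2-fold higher in the Tra2β IP, 615 at least 2-fold lower and 713 between. The median ratio was -0.53, with quartiles of -1.49 and 0.61. This split rested on the scaling. With the median of all probes the counts were 88 higher and 1475 lower, with quantile normalization 463 and 506, with normexp 111 and 1388, and with unscaled signals 16 and 1614. The median of all genes moved by -3.11, 0.49, -2.32 and -7.15 under these settings. Counts for gene lists below are under the main scaling, and with the median of all probes, normexp and unscaled signals no list had more genes higher or fewer lower. Quantile normalization moved counts both ways: 6 of 21 lists had more genes higher, 10 fewer lower and 3 more lower, among them ZNF genes with 23 higher against 18, hnRNPs with 6 lower against 10 and ribosomal proteins with 65 lower against 40. Of the 333 genes higher, 166 had an IgG signal under 1154, where any Tra2β signal above its floor is at least 2-fold higher under the main scaling. Without a filter on dim probes the counts were 8516 and 4011 and the median moved by 1.77. That setting lets in 4807 genes well above background on neither array, which can stand high from the scaling alone. CALCA, with signals of 4.03 in the IgG IP and 3.21 in the Tra2β IP, stood at 6.82. Of the 20 lists with a percentile 3 stood apart, where 5.0% of simulated lists without a shift did. Among 292 genes with more than 1 probe measured on both arrays, 113 (38.7%) had probes that went opposite ways.

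Of 15 known targets of Tra2 proteins on the array, 13 were well above background in the IgG IP and 5 of these (38.5%) in the Tra2β IP, where the median of lists matched on IgG signal was 23.1% (percentile 94.6). Among the 5, 1 was at least 2-fold higher and 0 lower. With the median of all probes and with normexp 1 was higher and 4 lower, and with unscaled signals 0 and 5. The detection floor limits these counts. SMN2 had an IgG signal of 96.3, and under 1154 any measured gene is at least 2-fold higher under the main scaling. CHEK1 had a Tra2β signal of 17.8, close to the floor of 16.3, and a target under that floor leaves the 5 and is not counted as lower. TRA2B itself, whose mRNA is bound and spliced by its own protein, had a signal of 20358 in the IgG IP and 120 in the Tra2β IP, a log2 ratio of -0.26. The spinal muscular atrophy gene SMN1 stood at 0.03 (-3.07 with the median of all probes, -3.31 with normexp and -7.11 unscaled), the checkpoint kinase gene CHEK1 at -0.90 and the adhesion receptor gene CD44 at -0.93. SMN2 stood at 4.86, and at -2.28 in unscaled signals, where it was lower in the Tra2β IP. With the stricter filter on dim probes SMN2 dropped out. SMN1 and SMN2 are near-identical copies, so their separate values are uncertain. The median of the 5 was -0.26, at percentile 64.7 of matched random lists, and it was -3.36 with the median of all probes, -3.18 with normexp and -7.40 unscaled. TRA2A, MAPT, CLTB, GNRH1, TUBD1, PPP1R12A and SGO2 were well above background in the IgG IP alone, at least 1.38-fold higher there for PPP1R12A and 1.23-fold for SGO2 and with no fold for the others under the main scaling, and HIPK3 and CALCA on neither array. In unscaled signals the bounds of those 7 ran from 3.18-fold (GNRH1) to 196-fold (PPP1R12A) lower in the Tra2β IP. BCL2, the remaining target well above background in the IgG IP alone, is described below.

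Among anti-apoptotic members of the BCL2 family, none was well above background in the Tra2β IP (0 of 6). BCL2, a mitochondrial inhibitor of apoptosis, had a signal of 163 in the IgG IP and 3.56 in the Tra2β IP, and its at-least fold was under 1 with the main scaling. In unscaled signals it was at least 10.02-fold lower in the Tra2β IP, so its direction rests on the scaling. With the main scaling MCL1 was at least 7.51-fold lower and BCL2L2 at least 1.76-fold lower in the Tra2β IP (1065-fold and 250-fold unscaled). BCL2L1 and BCL2A1 allowed no fold there, but at least 24.0-fold and 79.8-fold unscaled, and BCL2L10 was on neither array above background. Of the whole family of 24 on the array, 6 were measured on both arrays, 2 at least 2-fold higher and 1 lower, with a median of 0.22 (percentile 31.2), which was -2.88 with the median of all probes, -1.40 with normexp and -6.93 in unscaled signals. It was also below 0 with a stricter filter on dim probes (-0.20) and without one (-0.60, 7 higher and 10 lower of 24). The pro-apoptotic genes HRK, BBC3 and BAX stood at 2.54, 2.32 and 0.65 and BID at -1.92. HRK had an IgG signal of 428, and under 1154 any measured gene is at least 2-fold higher under the main scaling. Its Tra2β signal of 17.5 lay close to the floor of 16.3, and it dropped out with the stricter filter on dim probes. For HRK, BBC3 and BAX a single probe carried the Tra2β signal. Other probes had IgG signals of 949 (HRK), 7580 (BBC3) and 6294 (BAX) but were not well above background in the Tra2β IP. HRK, BBC3 and BAX were below 0 with the median of all probes and in unscaled signals, and BBC3 and BAX with normexp. Of the caspases, inhibitors of apoptosis and death receptor genes 5 of 26 were measured, 2 higher and 3 lower, with a median of -1.28 (percentile 11.1). The initiator caspase genes CASP8 and CASP10 stood at 6.50 and 5.91, and at -0.64 and -1.24 in unscaled signals, while the survivin gene BIRC5 stood at -2.28 and the cytochrome c gene CYCS at -1.35. For both caspases a single probe carried the Tra2β signal, and their other probes were not well above background there.

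SR protein and hnRNP genes, which encode splicing factors, were detected in the Tra2β IP more often than lists matched on IgG signal in 20 bins, the hnRNPs not under closer matching. Of 14 SR protein genes well above background in the IgG IP, 11 (78.6%) were in the Tra2β IP too, at percentile 99.5 of lists matched on IgG signal, where the median was 50%. Of 23 hnRNP genes 16 (69.6%) were, at percentile 98.4. Against lists of the nearest genes in IgG signal the percentiles were 99.5 and 96.9. Their ratios did not stand apart. The SR proteins had a median of -0.96 (percentile 59.0) with 1 higher and 5 lower of 11, among them SRSF7 at -2.82, SRSF9 at -2.09, SRSF5 at -1.71 and SRSF4 at 1.55, the last below 0 with the median of all probes, normexp and unscaled signals. The hnRNPs had a median of -1.14 (percentile 48.4) with 2 higher and 10 lower of 16, among them HNRNPM at -2.30, PCBP1 at -1.99, HNRNPD at -1.85 and HNRNPC at 2.00, the last also below 0 under those settings. A second measured HNRNPD probe stood at -0.15, and other HNRNPC probes at 0.05 and 1.44. Core spliceosome genes were detected in 16 of 33 cases (48.5%, percentile 91.5) and had 2 higher and 8 lower of 16 and a median of -0.95 (percentile 25.6), with U2AF1 at -3.99, SNRPD3 at -3.30, DHX15 at -2.31 and SF3B2 at -2.13.

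Ribosomal protein genes were detected in the Tra2β IP in 75 of 82 cases (91.5%, percentile 99.985 of lists matched on IgG signal, but 89.1 of lists of the nearest genes in IgG signal). Of the 75 measured, 6 were at least 2-fold higher and 40 lower, with a median of -1.12 (percentile 8.20). With quantile normalization 1 was higher and 65 lower, with a median of -2.66, and the percentile was 57.2 with 5 bins and 62.0 without a filter on dim probes. RPS19 at -4.89 and RPL18 at -4.78 followed RPS3 and RPS28. Nuclear genes of the respiratory chain and ATP synthase were detected in 41 of 77 cases (53.2%, percentile 38.0) and had 2 higher and 29 lower of 41 and a median of -1.57. At percentile 1.04 this list stood apart, below matched lists, but not with quantile normalization (10.5) or normexp (20.7). ATP5MG stood at -4.32, the complex I gene NDUFA8 at -3.51 and the cytochrome oxidase gene COX6A1 at -3.42. Housekeeping genes had 1 higher and 8 lower of 11 and a median of -1.73 at percentile 2.33, and 5 of the settings tried moved the ratio percentile inside the bounds. The tubulin genes TUBA1C and TUBA1B stood at -3.98 and -3.67, the enolase gene ENO1 at -3.52 and the aldolase gene ALDOA at 2.35, the last at -0.76 with the median of all probes and below 0 with normexp and unscaled signals.

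ZNF zinc finger genes, most of which encode DNA-binding repressors, leaned toward the Tra2β IP relative to other genes. Of 306 well above background in the IgG IP, 27 (8.82%) were detected in the Tra2β IP, at percentile 99.95 of matched lists, where 4.90% was the median. Of those 27, 18 were at least 2-fold higher and 1 lower, and their median of 1.55 stood apart at percentile 99.4. Matched lists had a median above 0 too (0.87). The count of 18 rests in part on the detection floor, since any measured gene with an IgG signal under 1154 is at least 2-fold higher under the main scaling. The list's median was -1.55 with the median of all probes, -0.68 with normexp and -5.60 in unscaled signals, so its sign rests on the scaling, and with normexp the list no longer stood apart (percentile 86.6). ZNF713 had signals of 7973 in the IgG IP and 11407 in the Tra2β IP, a log2 ratio of 7.66, and ZNF2 one of 7.46, and both were also higher in unscaled signals (0.52 and 0.31). The other probes of ZNF2 were not well above background in the Tra2β IP. ZNF146 stood at 4.16 and ZNF784 at 4.12, and both were below 0 in unscaled signals and dropped out with the stricter filter on dim probes. A brighter ZNF146 probe (1401 in the IgG IP) was not well above background in the Tra2β IP, and without a filter it put the gene at 0.69.

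**Figure D4:**
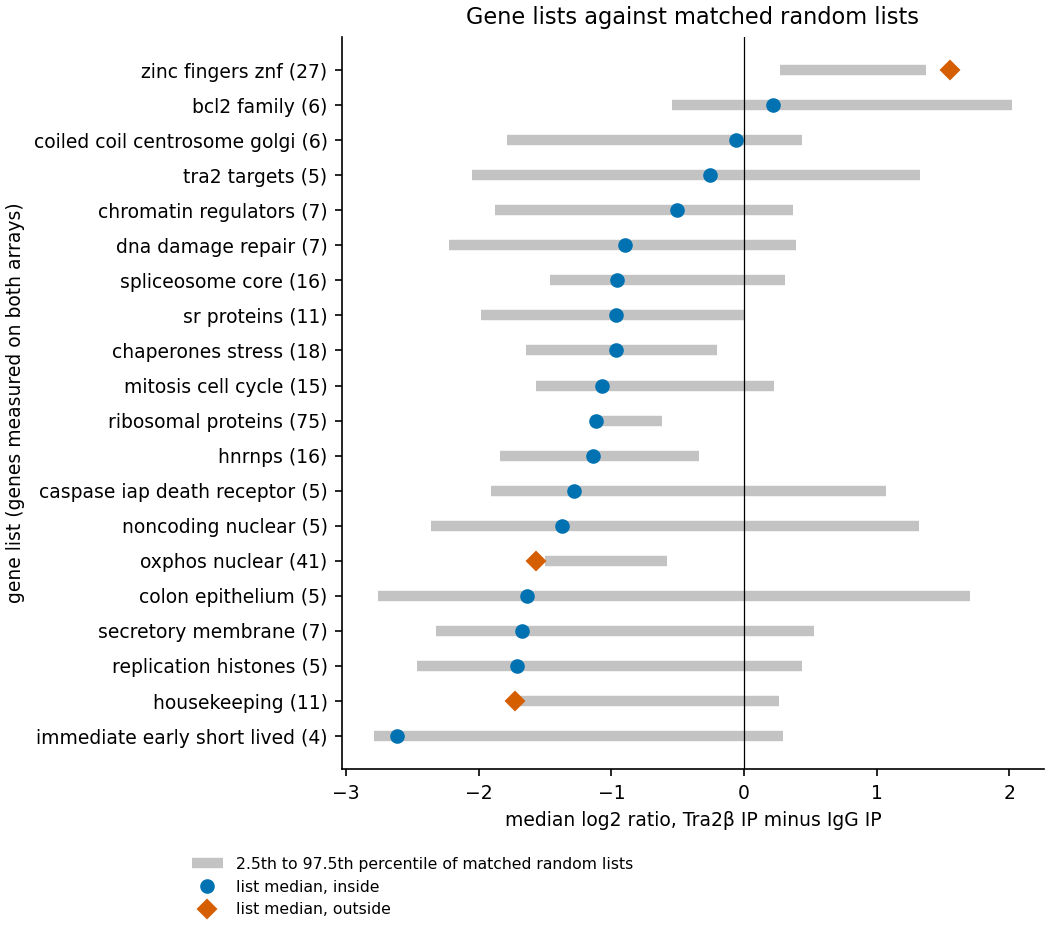
Median log2 ratio of the Tra2β IP over the IgG IP (x axis) for the 20 gene lists with a percentile (y axis, number of genes measured on both arrays in brackets), with grey bars for 10000 random lists matched on mean signal, less the outer 2.5% on each side. Diamonds mark the 3 lists outside their bar under the main scaling: ZNF zinc fingers at 1.55, nuclear respiratory chain genes at -1.57 and housekeeping genes at -1.73; the sign of the zinc finger median turns with the median of all probes, normexp and unscaled signals.

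Noncoding nuclear RNAs were detected in the Tra2β IP in 5 of 5 cases, at percentile 99.9 of lists matched on IgG signal. The nuclear speckle RNA MALAT1 had a log2 ratio of -4.64 at 1 of its 4 probes, the small nucleolar RNA hosts SNHG1 and SNHG5 -1.95 and -1.37, and MEG3 4.77, though -2.38 in unscaled signals. MEG3 had an IgG signal of 139, where any measured gene is at least 2-fold higher under the main scaling. It dropped out with the stricter filter on dim probes. The list's median of -1.37 lay at percentile 19, with 1 higher and 3 lower. Replication histone genes, whose mRNAs mostly lack a poly(A) tail, were measured in 5 cases, 0 higher and 4 lower, with a median of -1.71 (percentile 17.5). Without a filter on dim probes 30 were higher and 15 lower of 66, with a median of 0.80. Of the 66, 55 were well above background in the IgG IP and 5 in the Tra2β IP, so most of these ratios rest on dim signals. H3C15 stood at -3.00, H4C13 at -1.96, H4C2 at -1.71 and H4C3 at -1.55, and these close copies can share a probe. A second measured H3C15 probe stood at -0.60.

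Genes of growth and genome upkeep lay inside the range of matched lists. Cell cycle genes had 1 higher and 8 lower of 15 (median -1.07, percentile 18.3), with the helicase gene MCM7 at -2.96, CCNE1 at -2.50, TYMS at -2.46 and the kinesin gene KIF11 at 2.06. DNA repair genes had 0 higher and 3 lower of 7 (median -0.90, percentile 40.6), with MSH6 at -1.71, XRCC6 at -1.50 and PARP1 at -1.17. A second measured XRCC6 probe stood at -0.29. Chromatin regulators had 1 higher and 3 lower of 7 (median -0.51, percentile 73.9), with HDAC1 at -2.61, KMT2C at -1.38, SMARCC1 at -1.24 and SMARCA5 at 1.89. Coiled-coil proteins of centrosome and Golgi had 2 higher and 2 lower of 6 (median -0.06, percentile 85.0), with CENPF at -3.98, SMC3 at -1.39, CEP290 at 2.13 and SMC1A at 1.32. KIF11, SMARCA5, CEP290 and SMC1A were below 0 with the median of all probes, normexp and unscaled signals, and the medians of the last 2 lists were above 0 with quantile normalization (0.03 and 0.45).

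Stress, signalling and membrane genes with a percentile did not stand apart from matched lists under the main settings. Chaperone genes had 1 higher and 9 lower of 18 (median -0.97, percentile 45.2), with HSP90AB1 at -3.21, CCT8 at -2.40, HSPB1 at -2.24 and HSPE1 at -2.19. The immediate-early genes had 0 higher and 4 lower of 4 (median -2.62, percentile 3.78), namely IER2 at -3.76, ZFP36L1 at -2.79, DUSP6 at -2.44 and MYC at -1.21. Secretory and membrane genes had 1 higher and 4 lower of 7 (median -1.68, percentile 13.1), but stood apart at percentile 1.585 with the median over a gene's probes (median -2.36) and at 0.09 without a filter on dim probes, with LAMP1 at -4.69, MET at -2.88, CD63 at -2.47 and ITGB1 at -1.68. Of the Wnt and colorectal cancer genes 2 of 27 were measured, MYC among them, too few for a percentile. Colon epithelium genes had 1 higher and 3 lower of 5 (median -1.64, percentile 18.7), with the keratin genes KRT19, KRT18 and KRT8 at -3.51, -2.28 and -1.64 and the mucin gene MUC2 at 5.25, though -1.90 in unscaled signals. MUC2 had an IgG signal of 64.1, where any measured gene is at least 2-fold higher under the main scaling. Its Tra2β signal of 17.2 lay close to the floor of 16.3, and it dropped out with the stricter filter on dim probes. Without a filter on dim probes 15 of 24 colon epithelium genes were higher and 5 lower, with a median of 5.11. Only 11 of the 24 were well above background in the IgG IP, and a gene at background on both arrays stands high from the scaling alone. Markers of other cell types were well above background in 7 of 27 cases in the IgG IP and in 0 in the Tra2β IP, so that list has no ratio.

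Few genes were well above background in the Tra2β IP alone. There were 19, led by the salivary protein gene SMR3A at least 4774-fold higher, the pregnancy glycoprotein gene PSG2 at least 1796-fold, GLIPR1 at least 1449-fold, the collagen gene COL6A3 at least 1095-fold, ABHD1 at least 548-fold and the neuropeptide precursor gene PMCH at least 540-fold. These bounds rest on the main scaling, and in unscaled signals they were 33.7-fold for SMR3A, 12.7-fold for PSG2, 10.2-fold for GLIPR1, 7.72-fold for COL6A3, 3.86-fold for ABHD1 and 3.80-fold for PMCH. A second COL6A3 probe was well above background on neither array (3.95 in the IgG IP and 3.24 in the Tra2β IP). In the IgG IP alone there were 9845 genes, of which 1161 had a bound of 2-fold or more. The glutathione transferase gene GSTP1 was at least 71.2-fold lower in the Tra2β IP, RPS14 at least 55.0-fold, the histone gene H3-5 at least 44.8-fold and SDF2L1 at least 37.0-fold, with larger bounds in unscaled signals. With the scanner software's weaker mark for signal over background, 319 genes were marked in the Tra2β IP alone.

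Detection in the Tra2β IP went with brightness in the IgG IP. Of the 11512 genes well above background in the IgG IP, 14.5% were so in the Tra2β IP. With the genes in 10 groups of like size by IgG signal, the share was 1.82% in the dimmest group and 69.4% in the brightest, where 799 of 1152 were detected.

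**Figure D5:**
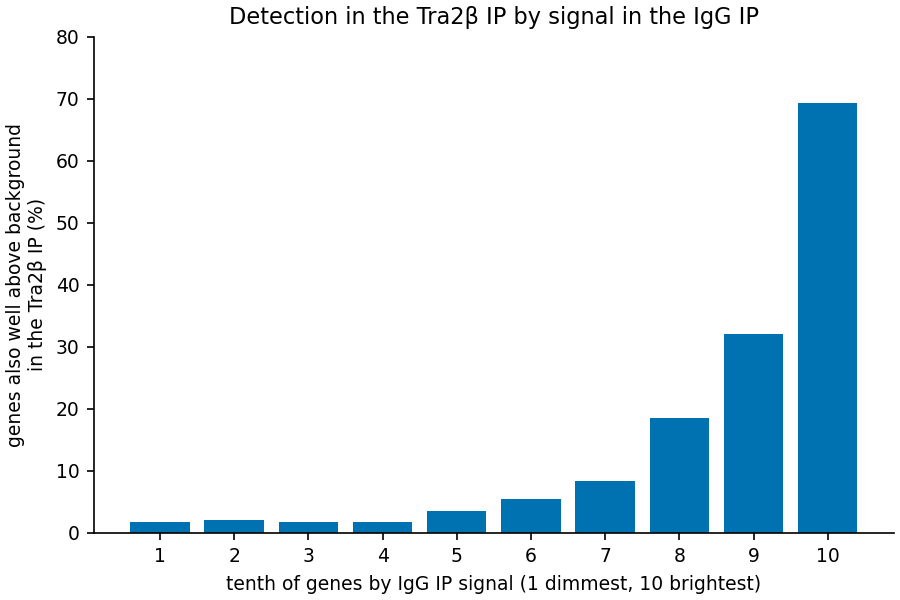
Share of genes well above background in the IgG IP that were also well above background in the Tra2β IP (y axis, percent), in 10 groups of genes ordered by IgG IP signal (x axis, group 1 dimmest), from 1 array per immunoprecipitation. The share is 1.82% in the dimmest group and 69.4% in the brightest.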

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

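The tests in this part were all chosen after the results were seen.

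Control probes that entered no comparison differed between the arrays: the brightest E1A spike-in probe had a signal of 290009 on the IgG array and 32.9 on the Tra2β array, and the bright-corner spots a median of 6183 and 157, and the Tra2β array had 3852 probes well above background against 24261. One factor that dimmed every probe alike is argued against for probes without a RefSeq match, of which 33.2% of those measured on both arrays had the higher unscaled signal in the Tra2β IP, and cannot be told for matched probes, where 1.39% did (29 of 2087). Lower RNA yield alone, with the spike-in added and labelled as on the IgG array, is argued against by the 7 other E1A probes well above background on the IgG array, whose median log2 ratio was at most -8.63. Their loss is part of the observation itself. They bear on the condition set for the spike-in and do not measure RNA yield. Exchanged labels cannot be told apart from the labels as given, because each label has 1 array, and the 5 Tra2 targets well above background on the Tra2β array do not decide it. A spike-in that was left out or not labelled, and a Tra2β precipitate that held few RNAs, stay open as untested explanations, and so does a difference in hybridisation or scanning, since the bright-corner spots were also dimmer.

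Probes without a RefSeq match, which no gene comparison used, were brighter in the Tra2β IP relative to each array's 75th percentile: 871 of 1331 measured on both arrays were at least 2-fold higher, with a median log2 ratio of 4.50 against -0.54 for matched probes (-2.64 and -7.69 unscaled, with 442 or 33.2% of the unmatched higher). Over 39 unmatched accessions with 2 probes well above background on both arrays, the Spearman correlation between the ratios of the 2 probes was 0.932. The median difference within a pair was 0.99 on the log2 scale, against 6.23 for random pairs. Matched pairs differed by 0.98, against 1.54 for random pairs. For these 39 accessions the values argue against signal caught by each bright probe on its own. Pairs with a probe dim on either array were left out, so for other accessions this cannot be told. Weak IgG signals set part of the count. Below 476, the median IgG signal of probes well above background on the IgG array, all 629 unmatched and all 107 matched probes were at least 2-fold higher. The detection floor requires this for any measured probe with an IgG signal under 1154. As the sole reason, weak IgG signals are argued against below 476 by an excess of 1.99 of unmatched over matched probes of the same IgG signal (bootstrap range 1.42 to 2.52). At or above 476 the excess was 0.52 (0.35 to 0.65), between the bounds set for and against them. There 34.5% of 702 unmatched and 15.5% of 1980 matched probes were at least 2-fold higher. The bootstrap ranges resample probes of 1 pair of arrays, which are not independent, so they hold for these arrays and do not cover spread between arrays. Below the median, 1 bin held as few as 9 matched probes. Sequence shared by the probes, such as a repeat, stays open, because no probe sequences were used, and so does material other than mRNA in the labelled sample. Binding of these transcripts by Tra2β is the biological explanation the design names, and it was not tested.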

How the results depend on the processing

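The shares detected, unscaled signals, the percentile over probes detected on both arrays and the restriction to genes whose probes agree were chosen after the data were seen. Counts of genes higher and lower in the Tra2β IP, 333 and 615, were 88 and 1475 with the median of all probes, 111 and 1388 with normexp, 8516 and 4011 without a filter on dim probes, 16 and 1614 in unscaled signals and 197 and 271 under the 4-fold size rule, and within 1.5 times under the other settings. By construction the median and unscaled settings shift every ratio by a constant, the unfiltered setting lets in 16338 genes, and the 4-fold rule is stricter; for normexp the cause was not tested. Genes above background in the Tra2β IP alone numbered 319 with the weaker detection mark, against 19. The log2 ratio of TRA2B, -0.26, was -3.36 with the median of all probes, -3.18 with normexp, -7.40 unscaled and -0.05 with quantile normalization, and did not turn. Of 220 percentiles of gene lists under alternatives that can move one, 194 stayed on the same side of the bounds; the median of all probes and the percentile over detected probes shift all ratios alike and cannot. Nuclear respiratory chain genes (1.04) moved to 10.54 with quantile normalization, 20.66 with normexp and 37.995, 21.625 and 30.66 by the share detected, by that share at the brightest IgG probe and by that share against the nearest genes. ZNF genes (99.43) moved to 86.605 with normexp. Housekeeping genes (2.325) moved to 5.755 with quantile normalization, 8.98 without a filter, 2.64 with a stricter filter, 2.69 without outlier spots, 6.565 with 5 bins, and 23.76, 5.775 and 6.115 by the 3 shares. Secretory and membrane genes (13.12) came to stand apart at 1.585 with the median over probes and 0.09 without a filter. By the 3 shares, a measure other than the ratio, SR proteins stood at 99.48, 99.625 and 99.505, hnRNPs at 98.39, 98.92 and 96.885, ribosomal proteins at 99.985, 99.995 and 89.1, and noncoding RNAs at 99.92, 99.935 and 99.73. The cause of the moves of list percentiles was not tested. Scaling on the E1A probes was not run, since 9 of 10 were not well above background on the Tra2β array. A block for the slide was not run because both arrays share 1 slide, and motif density was not run because no transcripts were used. BCL2 has no ratio under the filters, and without one it was 1.63, from a Tra2β signal of 3.56 that was not well above background. No paired analysis was possible because each group has 1 array and the result comes from no test. Signal over background limits the Tra2β IP, where 9.40% of probes were well above background and the rest have only a bound.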

Other observations

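The comparisons of probe classes, the test on Tra2 targets and those on carry-over in single gene lists were chosen after the data were seen, and the test on carry-over over all genes before its result was seen.

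The signal of the Tra2β IP was concentrated in probes whose accession had no match in the table of RefSeq genes, and no probe sequence was mapped to see which genes they target. Of its 100 brightest probes 97 had no RefSeq match, against 18 of the 100 brightest of the IgG IP, and 0 were shared. Those 100 probes held 66.1% of all signal in the Tra2β IP and 15.2% in the IgG IP. The brightest, chosen after its value was seen, was a probe of the cDNA clone BC071732, with a signal of 24.3 in the IgG IP and 92714 in the Tra2β IP, and a second probe of that clone went from 124 to 38195. Among unmatched probes measured on both arrays, those of GenBank mRNAs and ESTs were at least 2-fold higher in the Tra2β IP in 83.8% of 611 cases (median log2 ratio 7.23, 0.08 unscaled) and those of THC consensus sequences in 82.4% of 102 (median 6.23, -0.92 unscaled). Ensembl transcripts were in 41.8% of 141 cases (median 0.29, -6.85 unscaled) and probes with no accession but their name in 50.6% of 356 (median 1.13, -6.02 unscaled). RefSeq accessions missing from the gene table were in 29.8% of 121 (median -0.94, -8.09 unscaled). Within the probe series that holds most of the bright probes, 539 of 621 unmatched probes were at least 2-fold higher (86.8%), but 44 of 249 matched probes (17.7%), and in unscaled signals 348 (56.0%) and 4 (1.61%) were higher. In the other 2 series 48.6% of 185 and 46.1% of 525 unmatched probes were at least 2-fold higher (medians 0.89 and 0.51), and 11.9% and 13.7% were higher unscaled, so the bright unmatched probes lay mostly in 1 series. These shares of at least 2-fold higher rest on the main scaling, under which every measured probe with an IgG signal below 476 was at least 2-fold higher.

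Across probes, which are not independent replicates, the arrays ranked matched and unmatched probes differently. The Spearman correlation of log2 signal was 0.48 over the 2087 matched probes and -0.18 over the 1331 unmatched probes well above background on both arrays.

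Detection of named genes in the Tra2β IP went with the signal in the IgG IP: 1.82% were detected in the dimmest and 69.4% in the brightest of 10 groups, which held 799 (47.9%) of the 1667 detected. Carry-over of RNA in proportion to its abundance may account for part of this: within the 1152 genes brightest in the IgG IP the Spearman correlation of the 2 arrays was 0.49, between the bounds set for and against it. Against lists of the nearest genes in IgG signal, the share of ZNF genes lay at percentile 99.91. The bound set against carry-over alone was 99.89, for 1 of 22 lists. The random lists drawn are too few to resolve so small a gap, so carry-over alone is not decided for ZNF genes. The hnRNP (96.89) and ribosomal protein genes (89.1) lay inside the range that carry-over needs. SR protein genes (99.5) and noncoding nuclear RNAs (99.73) lay between that range and that bound. Binding of known Tra2 target mRNAs was tested by the share of the Tra2 targets detected in the Tra2β IP, 5 of 13, which lay at percentile 94.6 of lists matched on IgG signal, short of the bound set for it and above the bound set against it. For all genes and for the Tra2 targets carry-over and binding cannot be told apart here, since 1 array per group leaves both values without a replicate and the list holds 13 genes.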
